A study of Mus musculus with 20 samples.

How the data were processed

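Messenger RNA was sequenced from phalanges, the segments of the digits, of mouse embryos at embryonic day 16 and embryonic day 17 (E16 and E17). Per the labels, each library was a pool of 20 embryos at E16 and of 10 embryos at E17. Each stage gave 10 libraries, from the distal and proximal phalanx of digit 1 and the distal, middle and proximal phalanx of digit 2, in the forelimb and in the hindlimb. These 5 anatomical samples are called elements. There was 1 library per stage, limb and element, so no combination was replicated. Each library was placed in its group from the labels, and all 20 were used. Per the labels' protocols, libraries were made with a kit that is not marked as strand-specific, so sense and antisense transcripts of a locus cannot be separated.

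The deposited count tables, 1 per stage, hold whole-number counts per gene symbol. The submitters' processing notes name the GRCm39 genome build, HISAT2 2.2.1 and StringTie 2.1.7, and the notes do not give the counting step, the annotation release or any filter. A second pair of deposited tables holds a TMM-normalised signal. In rows of at least 100 counts, each of its columns equalled the matching count column divided by a single constant, with a largest deviation of 5.4e-08%, and the implied factors ranged from 0.939 to 1.04. That scaling was set within each stage, so the deposited signal was not used to compare stages.

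The E16 table holds 27527 rows with 27067 distinct symbols and the E17 table holds 28766 rows with 28326 distinct symbols. Rows were joined by symbol. Of the joined genes, 23932 were written alike in both tables and 58 were matched through synonyms of the RefSeq table of assembly GRCm38.p6, giving 23990 genes. The joined genes held 99.03% to 99.48% of the counts of each library. Symbols found in the E16 table only numbered 3077 and held 0.57% of its counts, and symbols found in the E17 table only numbered 4336 and held 0.85%. Rows with an assembler's locus name held 0.019% of the E16 counts and 1.08% of the E17 counts. No coordinates were used, since the reference held the earlier build GRCm38.

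Genes at 1 CPM or more in at least 4 libraries were tested, which left 14872 genes. Counts were modelled with edgeR 4.0.16 in R 4.3.3, with TMM factors over all 20 libraries and quasi-likelihood F tests. The 8 two-group comparisons came from 1 fit with terms for element, stage and limb and 13 residual degrees of freedom. Interactions of stage with position, stage with limb and limb with digit were tested in fits of their own, with 9, 12 and 9 residual degrees of freedom. The Benjamini-Hochberg adjusted p threshold was 0.05 within each comparison. The common biological coefficient of variation was 18.5% and the median prior degrees of freedom were 4.56. All tests were two-sided. A fold change is given on the log2 scale with its standard error. CPM values are scaled by the TMM factors and given as mean ± SD over the libraries of a group, which differ from each other in the remaining factors. A matched pair is 2 libraries alike in all but the factor compared.

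The p-values rest on agreement between matched libraries and not on replicate litters. The labels give the number of embryos pooled for each library and do not say whether the libraries of a stage came from the same embryos. Stage cannot be told apart from the embryos pooled, pool size, count table or sequencing run. A gene at 0 in every library of a group was given a floor of 3 counts over that group, and its fold is written as a lower bound. The interaction fits used no such floor. Shares of counts of single libraries carry Wilson intervals at the 95% level. Floors and intervals cover counting error only, since reads without molecular identifiers are not independent molecules.

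Gene lists were tested with limma 3.58.1 camera, with a preset correlation of 0.01 between genes, adjusted over lists within a comparison, and again with an estimated correlation. The 27 lists hold 362 members, of which 338 were measured. They cover cartilage matrix, hypertrophic cartilage, osteoblast and bone matrix, osteoclast, joint and articular, tendon and ligament, skeletal muscle, epidermis, nail and hard keratin, distal digit tip patterning, HoxD and HoxA 5-prime genes, HoxC genes, limb identity and anterior-posterior digit patterning. They also cover Hedgehog response, BMP response, canonical Wnt response, FGF response, cell cycle, endothelium, erythroid, macrophage, Schwann cell and nerve, melanocyte, immediate early and heat shock, mitochondrially encoded and sex-linked genes. Over the 8 comparisons and the 26 lists other than the sex-linked list, 81 of 208 tests passed with the preset correlation and 8 of 208 with the estimated correlation.

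The place of the proximal phalanx of digit 1 between the middle and proximal phalanges of digit 2 was measured in 2 ways within each stage and limb set. The first was the root mean square difference of log2 CPM (prior count 2) over the tested genes. The second was a projection on the digit 2 axis, where 0 is digit 2 proximal and 1 is digit 2 middle, over genes chosen in a fit without the 5 libraries of the set scored. Both were tested by exact sign flips over the 4 sets, for which the smallest possible p is 0.125.

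The samples, comparisons, tests, lists, alternatives and the rule for naming genes were fixed before the data were examined. In each of the 8 comparisons the rule names the 8 highest and 8 lowest fold changes among genes past the threshold with an average log2 CPM of 2 or more, the same sign in every matched pair and a symbol that is not a predicted gene. It adds the 3 members with the smallest adjusted p of each list past camera, 2 members of lists not past it, 21 genes chosen in advance, and the 5 genes with the smallest adjusted p of each interaction.

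The alternatives set in advance were RLE size factors, no filter on low counts, DESeq2 1.42.0, each stage alone, each limb alone, leaving out each library in turn, a prior count of 10, the 200 genes with the smallest p for the digit 2 axis, and the estimated correlation. Leaving out the 2 forelimb digit 1 proximal libraries, the genes with a single annotated exon or the muscle list was chosen after seeing the data. Other splits of the libraries into groups of the same sizes were also run. Exon numbers came from GENCODE release M21.

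The code was tested on simulated counts, with 200 of 14872 genes changed. They were drawn from the mean of each gene over the 20 libraries and from the real library sizes. Genes were drawn independently and without other effects of stage, limb or element. The shares below therefore do not cover tissue differences that move many genes together. For the stage comparison edgeR recovered 80.6%, 97% and 97% of genes changed 1.5-fold, 2-fold and 4-fold. For digit 1 proximal against digit 2 proximal the shares were 61.2%, 74.6% and 95.5%, with 3.75% false calls, against 14.1% false calls for DESeq2. For the stage by position interaction they were 28.4%, 59.7% and 89.4%, for the stage by limb interaction 38.8%, 70.1% and 87.9%, and for the limb by digit interaction 22.4%, 41.8% and 86.4%. Simulated positions of 0, 0.25, 0.5 and 1 on the digit 2 axis were recovered as 0.0589, 0.257, 0.474 and 0.955.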

Results

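Transcripts were counted in 20 mouse phalanx libraries, 10 from E16 and 10 from E17. At each stage there was 1 library of digit 1 distal, digit 1 proximal, digit 2 distal, digit 2 middle and digit 2 proximal from the forelimb and 1 of each from the hindlimb. Total counts per library ranged from 70871735 to 77361898 at E16 and from 75278309 to 111204552 at E17. The 10 most abundant genes took 4.56% to 6.01% of the counts at E16 and 7.82% to 10.26% at E17. Xist and genes of the Y chromosome were present in all 20 libraries.

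Element took 48.3% of the sum of squares of log2 CPM, stage 25.4% and limb 6.52%. The first principal component held 41.9% of the variance and set the distal phalanges apart from the others. The second held 23.6% and set the stages apart.

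**Figure D1:**
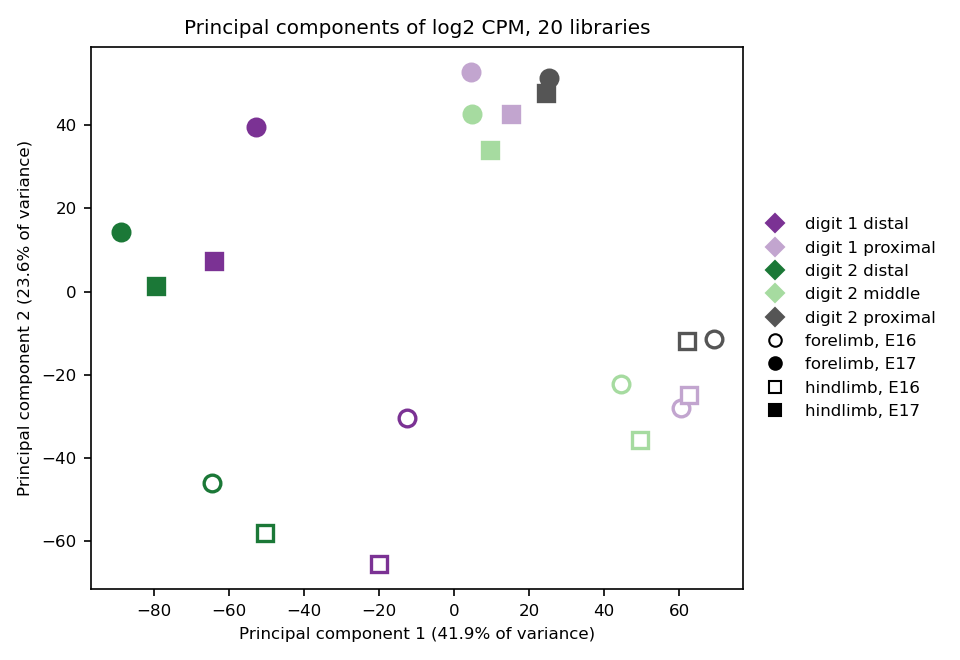
Principal components 1 and 2 of log2 CPM for the 20 libraries, with 1 point per library, colour for the element, shape for the limb and filled points for E17. The distal phalanges lie on the left, and within each element the E17 libraries lie above the E16 libraries.

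The stage comparison asked what changed in the phalanges between E16 and E17. Transcripts of epidermal differentiation rose and transcripts of cartilage matrix fell. Krt10, a keratin of differentiating epidermis, went from 5090 ± 1360 CPM at E16 to 18300 ± 4050 CPM at E17 (n = 10 per stage), a log2 fold change of 1.86 ± 0.11 (SE, adjusted p = 8.91e-10) that was higher in 10 of 10 matched pairs. Sox9, the transcription factor that directs chondrocyte formation, went from 82.4 ± 20.9 to 26.2 ± 4.52 CPM (log2 fold change -1.63 ± 0.12, adjusted p = 3.62e-09). Col2a1, the main collagen of cartilage, went from 466 ± 215 to 131 ± 44.4 CPM (log2 fold change -1.76 ± 0.14, adjusted p = 1.5e-08), and both genes were lower in 10 of 10 pairs.

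In the epidermis list 13 of 16 measured members rose, as many as when adjusted over the list alone, with a median log2 fold change of 0.84 (camera adjusted p = 0.00013, and adjusted p = 0.661 with an estimated correlation). Sbsn and Krtdap, secreted proteins of the suprabasal epidermis, rose by 2.24 ± 0.16 and 1.41 ± 0.11 on the log2 scale. Late cornified envelope genes held 7 of the 8 highest fold changes, among them Lce1m (6.5 ± 0.72), Lce1a1 (5.96 ± 0.7) and Lce1c (5.95 ± 0.59), each higher in 10 of 10 pairs. The Lce1 genes are close paralogs, so the counts of single members are uncertain. In the cartilage matrix list 15 of 18 members fell and 1 rose, also when adjusted over the list alone (median -0.89, adjusted p = 0.0011, and adjusted p = 0.661 with an estimated correlation). Matn3 and Matn1, matrilins of the cartilage matrix, were among the 8 lowest fold changes at -2.45 ± 0.28 and -2.37 ± 0.44. Ihh, a signal from maturing chondrocytes, fell by 2.77 ± 0.66 on the log2 scale (adjusted p = 0.00129, lower in 9 of 10 pairs).

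Several patterning genes fell. In the anterior-posterior digit patterning list 16 of 26 members fell, the same number adjusted over the list alone (median -0.58, adjusted p = 0.00388, and adjusted p = 0.595 with an estimated correlation). Dach1 was at -1.47 ± 0.09, Gli3 at -1.14 ± 0.1 and Lhx2 at -0.87 ± 0.07. In the Hedgehog response list 5 of 7 members fell, 5 adjusted over the list alone (median -1.08, adjusted p = 0.0424, and adjusted p = 0.595 with an estimated correlation). Ptch1, the Hedgehog receptor, and Hhip, a Hedgehog-binding protein, fell by 1.08 ± 0.13 and 1.16 ± 0.14 on the log2 scale. Hoxd13 and Msx1 also fell, by 1.01 ± 0.13 and 1 ± 0.09. In the cell cycle list 10 of 20 members fell and 1 rose, alike adjusted over the list alone (median -0.16, adjusted p = 0.0425, and adjusted p = 0.661 with an estimated correlation). Top2a and Mki67, made in dividing cells, were at -0.83 ± 0.07 and -0.87 ± 0.11.

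In the skeletal muscle list 14 of 16 members rose, 14 adjusted over the list alone (median 2.11, adjusted p = 0.00324, and adjusted p = 0.661 with an estimated correlation). Ckm, muscle creatine kinase, was at 2.57 ± 0.29 and Tnnc2, a fast troponin, at 2.93 ± 0.39. Muscle transcripts took 0.0195% ± 0.0398 of the counts at E16 and 0.0656% ± 0.127 at E17 (n = 10 each), with 1 forelimb digit 1 proximal library as the highest of each stage. In the immediate early and heat shock list, genes induced by stimulation or stress, 11 of 14 members rose, 11 adjusted over the list alone (median 0.38, adjusted p = 0.0023, and adjusted p = 0.595 with an estimated correlation). Junb rose by 1.34 ± 0.13 and Fos by 0.82 ± 0.08. Among the mitochondrially encoded genes 8 of 10 fell, against 9 down and 1 up adjusted over the list alone (median -0.46, adjusted p = 0.0425, and adjusted p = 0.661 with an estimated correlation). ND1 fell by 0.68 ± 0.1. Cebpb, a transcription factor, was the lowest fold change at -3.52 ± 0.16 (8.11 ± 1.51 against 94.3 ± 26 CPM). A difference of counting or annotation between the count tables was not tested for this gene. The FGF response list was not past the test, with 4 of 10 members lower, 4 adjusted over the list alone (median -0.13, adjusted p = 0.149), Spred1 among them at -0.75 ± 0.05.

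AY036118 had the highest fold change, 9.19 ± 0.27, which may come from gene names that differed between the count tables. In the E16 table a gene absent from the E17 table, Gm26917, stood at 1710 ± 357 CPM (without TMM scaling, n = 10), where AY036118 stood at 2.98 ± 0.737 CPM. Genes with a single annotated exon leaned down at E17, with 147 of 389 lower and 113 higher (median -0.13). In all, edgeR called 9788 of 14872 genes (65.8%), 4790 higher and 4998 lower at E17, of which 845 and 209 differed at least 2-fold. Each stage had a pool size and a count table of its own, so no value within a batch could be had.

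The limb comparison asked how hindlimb and forelimb phalanges differed. Regulators of limb identity differed strongly, while Hoxa9 had the smallest adjusted p in edgeR (7.41e-09). Pitx1, which specifies the hindlimb, stood at 36.6 ± 25.7 CPM in the hindlimb and 1.91 ± 2.12 CPM in the forelimb (n = 10 each, log2 fold change 4.65 ± 0.57, adjusted p = 6.24e-05). Tbx4, a hindlimb T-box factor, stood at 57.5 ± 9.04 against 14.5 ± 5.49 CPM (2.07 ± 0.15, adjusted p = 3.58e-07). Tbx5, its forelimb counterpart, stood at 6.14 ± 4.68 against 96.3 ± 55.6 CPM (-4.06 ± 0.32, adjusted p = 5.7e-07), and all 3 differed in the same direction in 10 of 10 pairs.

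Several Hox genes were higher in the hindlimb. Hoxa7, Hoxa3, Hoxa9 and Hoxb9 were among the 8 highest fold changes, at 3.12 ± 0.19, 2.03 ± 0.16, 1.82 ± 0.1 and 1.39 ± 0.15. In the list of HoxD and HoxA 5-prime genes 4 of 12 members rose, 4 adjusted over the list alone (median 0.18, adjusted p = 0.00455, and adjusted p = 0.308 with an estimated correlation). They included Hoxa10 (0.53 ± 0.05), Hoxa13 (0.44 ± 0.1) and Hoxa11os (0.51 ± 0.11), an antisense transcript that counts of unknown strand do not separate from Hoxa11. In the HoxC list 3 of 7 rose, 3 adjusted over the list alone (median 0.23, adjusted p = 0.0237, and adjusted p = 0.186 with an estimated correlation). Hoxc10 was at 0.66 ± 0.15. Hoxc6 and Hoxc9, the other members called, both lost their calls without E16 forelimb digit 1 distal (adjusted p = 0.0568 and 0.0659), and in 12 and 13 of the 20 single omissions. The limb identity list itself holds genes of both limbs, with 4 of 7 higher and 2 lower, or 5 and 2 adjusted over the list alone (median 0.46, adjusted p = 0.0694).

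Cell cycle genes were slightly higher in the hindlimb, 16 of 20 and 18 of 20 adjusted over the list alone (median 0.28, adjusted p = 4.43e-13, and adjusted p = 0.103 with an estimated correlation). Cdk1 stood at 84.2 ± 5.65 against 65.9 ± 6 CPM (0.35 ± 0.04, adjusted p = 9.03e-05) and Tyms, which makes thymidylate for DNA synthesis, at 50.7 ± 2.67 against 39.9 ± 2.32 CPM (0.35 ± 0.04, adjusted p = 1.99e-05), both higher in 10 of 10 pairs.

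Some genes of bone, tendon and nerve were lower in the hindlimb. In the osteoblast and bone matrix list 6 of 13 fell and 1 rose, alike adjusted over the list alone (median -0.3, adjusted p = 0.0105, and adjusted p = 0.103 with an estimated correlation). Col1a1 went from 6070 ± 2410 to 3990 ± 1480 CPM (-0.59 ± 0.05). In the osteoclast list 3 of 8 fell, 3 adjusted over the list alone (median -0.21, adjusted p = 0.0105, and adjusted p = 0.105 with an estimated correlation). Itgb3 fell by 0.76 ± 0.09 on the log2 scale. In the tendon and ligament list 6 of 11 fell, 6 adjusted over the list alone (median -0.22, adjusted p = 0.00133, and adjusted p = 0.103 with an estimated correlation). Kera fell by 0.62 ± 0.12. In the Schwann cell and nerve list 7 of 12 fell, 9 adjusted over the list alone (median -0.48, adjusted p = 0.000202, and adjusted p = 0.103 with an estimated correlation). Sox10, the glial regulator, was at -0.78 ± 0.13. Some cartilage genes were higher in the hindlimb, among them Col2a1 (0.65 ± 0.14, adjusted p = 0.00488), Col9a3 (0.77 ± 0.14) and Col9a2 (0.8 ± 0.15). Comp, another gene of the cartilage matrix list, was lower (-1.32 ± 0.28, adjusted p = 0.00427). Col2a1 also fell between E16 and E17, and whether the limbs differed in maturity was not tested.

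In the macrophage list 4 of 12 fell, 6 adjusted over the list alone (median -0.27, adjusted p = 0.0105, and adjusted p = 0.43 with an estimated correlation). Mrc1 fell by 0.49 ± 0.13. In the melanocyte list 2 of 4 fell, 2 adjusted over the list alone (median -0.85, adjusted p = 0.0105, and adjusted p = 0.186 with an estimated correlation). Pmel fell by 1.39 ± 0.26. Among the mitochondrially encoded genes 9 of 10 fell, 9 adjusted over the list alone (median -0.39, adjusted p = 0.000314, and adjusted p = 0.387 with an estimated correlation). ND4 fell by 0.47 ± 0.11. The sex-linked list was not past the test, with 2 of 5 lower, 2 adjusted over the list alone (median -0.18, adjusted p = 0.0509).

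The skeletal muscle list was past the test (median -0.75, adjusted p = 0.00133, and adjusted p = 0.601 with an estimated correlation), with 2 of 16 members called over all genes and no member adjusted over the list alone. These 2 were Neb (-2.03 ± 0.67, adjusted p = 0.0399) and Ttn (-1.83 ± 0.62, adjusted p = 0.0429), and both calls ended without E16 forelimb digit 1 distal (adjusted p = 0.0536 and 0.0554), among other libraries. The highest muscle shares were in the forelimb digit 1 proximal libraries, 0.132% (95% interval 0.131 to 0.133) at E16 and 0.422% (0.42 to 0.423) at E17, against 0.00559% (0.00542 to 0.00576) and 0.0175% (0.0173 to 0.0178) in the hindlimb. Over all genes edgeR called 3143, 1474 higher and 1669 lower in the hindlimb, of which 52 and 130 differed at least 2-fold. Within a stage the counts were 1560 genes at E16 and 188 at E17.

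**Figure D2:**
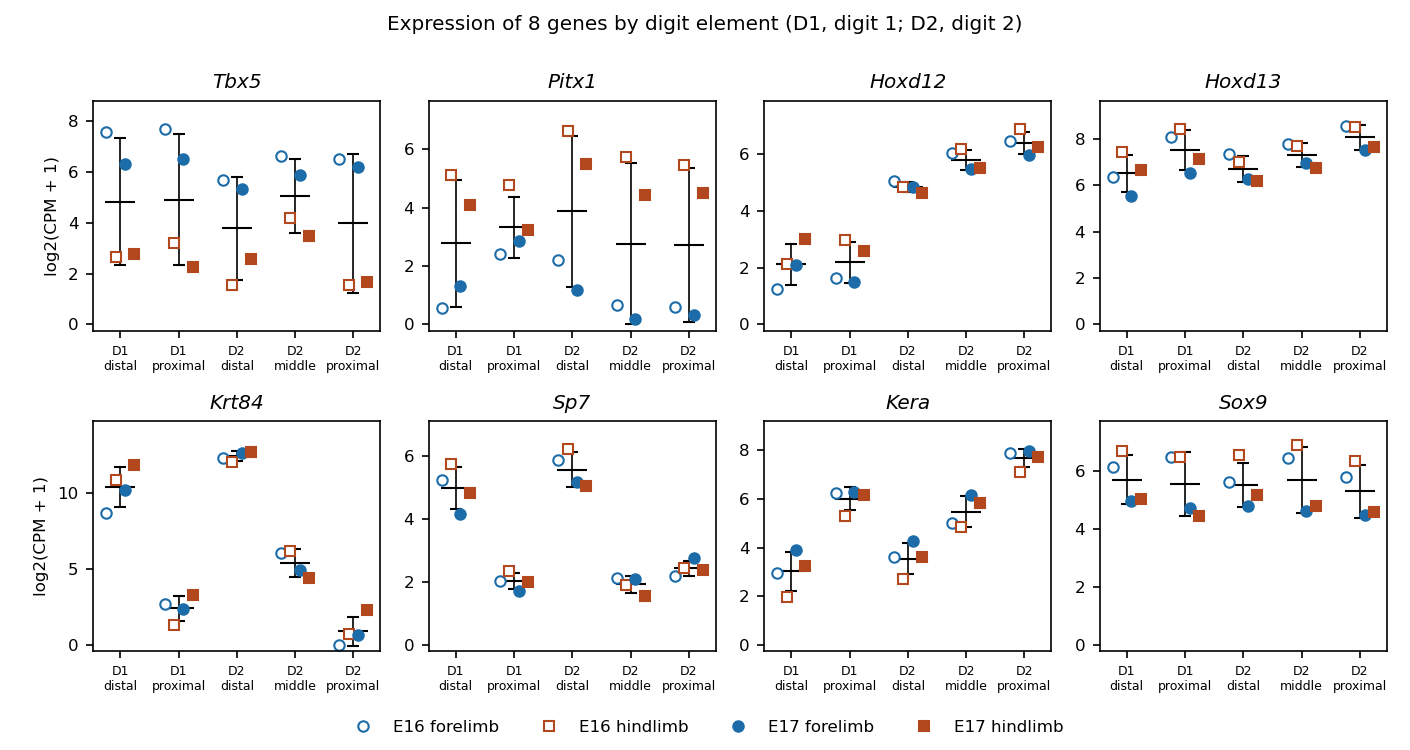
Expression of 8 genes in log2(CPM + 1), with 1 point per library, colour and shape for the limb, filled points for E17, and black bars for the mean ± SD of the 4 libraries of an element. Pitx1 and Tbx5 part by limb, Hoxd12 is lower in digit 1, Krt84 and Sp7 are high in the distal phalanges, Kera is high in digit 2 proximal and Sox9 parts by stage.

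The position comparison asked how distal phalanges, which carry the nail, differed from proximal ones, averaged over both digits. Hard keratins and several digit tip regulators were higher distally, and tendon genes were lower. Krt84, a keratin of the nail, stood at 3780 ± 2430 CPM in distal and 3.09 ± 2.98 CPM in proximal phalanges (n = 8 each, log2 fold change 10.35 ± 0.66, adjusted p = 1.2e-09). Msx1, a homeobox gene of the digit tip, stood at 365 ± 165 against 50.9 ± 24.9 CPM (2.86 ± 0.11, adjusted p = 4.96e-12). Sp7, the osteoblast transcription factor, stood at 41.6 ± 18.5 against 3.79 ± 1.07 CPM (3.37 ± 0.2, adjusted p = 5.55e-10), and Kera, the tendon and cornea proteoglycan keratocan, at 9.79 ± 4.93 against 138 ± 84.3 CPM (-3.72 ± 0.15, adjusted p = 1.06e-11). Each differed in the same direction in 8 of 8 pairs.

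In the nail and hard keratin list 15 of 16 members rose and 1 fell, alike adjusted over the list alone (median 5.62, the same with a member at 0 placed at its bound, adjusted p = 1.43e-09, and adjusted p = 0.0835 with an estimated correlation). Krt35 stood at 323 ± 167 against 3.11 ± 1.53 CPM and Hoxc13, a regulator of hair and nail keratins, at 140 ± 56.3 against 10.6 ± 4.65 CPM. Krt81 and Krtap3-1, a keratin-associated protein, had no counts in the 8 proximal libraries and were at least 14100-fold and 22900-fold higher in distal phalanges. Krt81 was below 20 CPM in some digit 2 distal libraries. Ambn, known as an enamel matrix protein, was at least 2230-fold higher. Krtap genes resemble each other, so counts of single members are uncertain. In the epidermis list 13 of 16 rose, 13 adjusted over the list alone (median 0.52, adjusted p = 5.26e-05, and adjusted p = 0.425 with an estimated correlation). Epcam rose by 0.95 ± 0.06.

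In the distal digit tip patterning list 12 of 19 rose and 5 fell, alike adjusted over the list alone (median 0.71, adjusted p = 0.000225, and adjusted p = 0.0835 with an estimated correlation). Msx2 was at 3.27 ± 0.11. In the BMP response list 9 of 11 rose and 1 fell, alike adjusted over the list alone (median 0.98, adjusted p = 0.000332, and adjusted p = 0.0888 with an estimated correlation). Bambi, a decoy receptor of BMP signals, was at 2.19 ± 0.1 and Smad7 at 0.98 ± 0.09. In the hypertrophic cartilage list 7 of 12 rose and 1 fell, alike adjusted over the list alone (median 1.12, adjusted p = 0.00472, and adjusted p = 0.0835 with an estimated correlation). Alpl, the phosphatase of mineralising tissue, was at 2.2 ± 0.18 and Ibsp, a bone sialoprotein, at 2.15 ± 0.24. In the osteoblast and bone matrix list 8 of 13 rose and 5 fell, alike adjusted over the list alone (median 1.12), and the list was not past the test (adjusted p = 0.238). Its share of counts was lower in distal phalanges, 0.72% ± 0.145 against 1.31% ± 0.389 in proximal ones of digit 1 and 0.78% ± 0.151 against 1.66% ± 0.41 of digit 2 at E16 (n = 2 each). At E17 it was 0.592% ± 0.0919 against 1.09% ± 0.332 and 0.702% ± 0.124 against 1.48% ± 0.283. Erythroid genes rose in 10 of 10 members, 10 adjusted over the list alone (median 1.13, adjusted p = 3.98e-05, and adjusted p = 0.337 with an estimated correlation). Alas2 rose by 1.2 ± 0.14 with 7 of 8 pairs higher. The globin genes Hba-a1 and Hba-a2 are near copies, so their separate counts are uncertain.

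In the tendon and ligament list 10 of 11 fell, 10 adjusted over the list alone (median -1.17, adjusted p = 8.39e-07, and adjusted p = 0.00665 with an estimated correlation). Dcn fell by 1.72 ± 0.12 and Col3a1 by 1.31 ± 0.04. In the joint and articular list 11 of 17 fell and 2 rose, or 12 and 2 adjusted over the list alone (median -0.96, adjusted p = 0.000804, and adjusted p = 0.142 with an estimated correlation). Thbs4 was at -3.25 ± 0.3 and Gdf6 at 2.28 ± 0.19. Gdf5, the marker of forming joints, fell by 1.64 ± 0.23. In the cartilage matrix list 11 of 18 fell and 1 rose, or 11 and 2 adjusted over the list alone (median -0.78, adjusted p = 0.0178, and adjusted p = 0.485 with an estimated correlation). Col11a1 was at -1.41 ± 0.08. All 12 endothelium members fell, 12 adjusted over the list alone (median -0.72, adjusted p = 3.77e-08, and adjusted p = 0.0753 with an estimated correlation). Cdh5, the cadherin of endothelial junctions, was at -0.85 ± 0.05. In the macrophage list 11 of 12 fell, 12 adjusted over the list alone (median -0.87, adjusted p = 2.47e-05, and adjusted p = 0.178 with an estimated correlation). Cx3cr1 was at -0.85 ± 0.09.

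The count for position was 6954 genes in edgeR, 3470 higher and 3484 lower in distal phalanges, of which 620 and 969 differed at least 2-fold. Within a stage it was 4287 genes at E16 and 4819 at E17.

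Digit 2 has 3 phalanges, and the next comparison set its middle phalanx against its proximal one. The middle phalanx libraries had more nail keratin and less of several tendon and joint genes. Krt84 stood at 47.1 ± 26.6 CPM in the middle and 1.24 ± 1.72 CPM in the proximal phalanx (n = 4 each, log2 fold change 5.61 ± 0.82, adjusted p = 0.000743), and Krt36 at 39.3 ± 20.1 against 1.76 ± 1.66 CPM (4.78 ± 0.64, adjusted p = 0.000371). Thbs4, a matrix protein of tendon and joint, stood at 4.98 ± 2.24 against 42.6 ± 7.17 CPM (-3.25 ± 0.42, adjusted p = 0.000325), and Kera at 46.6 ± 20.5 against 210 ± 49.6 CPM (-2.24 ± 0.2, adjusted p = 1.01e-05). These 4 genes differed in the same direction in 4 of 4 pairs. Krt84 in the middle phalanx was at 0.821% of its digit 2 distal level. Carry-over of distal tissue could not be told apart from expression in the middle phalanx itself.

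In the nail and hard keratin list 4 of 16 rose, 4 adjusted over the list alone (median 0.4, the same with a member at 0 placed at its bound, adjusted p = 0.00138, and adjusted p = 0.366 with an estimated correlation). Hoxc13 was at 1.37 ± 0.26 and Krt17 at 1.17 ± 0.2. In the distal digit tip patterning list 5 of 19 rose, against 9 up and 3 down adjusted over the list alone (median 0.12, adjusted p = 0.00489, and adjusted p = 0.241 with an estimated correlation). Tfap2b was at 1.41 ± 0.11, Msx2 at 1.13 ± 0.15, Wnt5a at 0.99 ± 0.14 and Msx1 at 0.94 ± 0.14. In the canonical Wnt response list 3 of 13 rose and 1 fell, alike adjusted over the list alone (median 0.17, adjusted p = 0.0243, and adjusted p = 0.424 with an estimated correlation). Wif1, a secreted Wnt inhibitor, rose by 1.15 ± 0.12. The calls of Nkd2 and Tcf7 ended without E16 forelimb digit 2 middle (adjusted p = 0.0579 and 0.0724), and in 5 and 7 of the 20 single omissions. In the epidermis list 2 of 16 rose, 4 adjusted over the list alone (median 0.21, adjusted p = 0.00336, and adjusted p = 0.582 with an estimated correlation). Epcam rose by 0.47 ± 0.08. The call of Krt5, the other member, ended without the same library (adjusted p = 0.151), and in 14 omissions. In the HoxC list 2 of 7 rose, 3 adjusted over the list alone (median 0.23, adjusted p = 0.0404, and adjusted p = 0.329 with an estimated correlation). The call of Hoxc12 also ended without that library (adjusted p = 0.056). The limb identity list was past the test with no member called and 1 higher adjusted over the list alone (median 0.23, adjusted p = 0.0404, and adjusted p = 0.241 with an estimated correlation).

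In the tendon and ligament list 3 of 11 fell, against 6 down and 1 up adjusted over the list alone (median -0.44, adjusted p = 0.000176, and adjusted p = 0.0273 with an estimated correlation). Dcn fell by 0.91 ± 0.16. In the joint and articular list 3 of 17 fell, against 4 down and 2 up adjusted over the list alone (median -0.32, adjusted p = 0.036, and adjusted p = 0.424 with an estimated correlation). Prg4, the lubricin of joint surfaces, was at -3.48 ± 0.64. In the cartilage matrix list 4 of 18 fell, 4 adjusted over the list alone (median -0.18, adjusted p = 0.0243, and adjusted p = 0.582 with an estimated correlation). Epyc fell by 2.55 ± 0.49. In the osteoclast list 1 of 8 fell, 2 adjusted over the list alone (median -0.26, adjusted p = 0.0154, and adjusted p = 0.23 with an estimated correlation). That gene was Ctsk, the protease that resorbs bone, at -0.57 ± 0.11. In the melanocyte list 1 of 4 fell, 2 adjusted over the list alone (median -0.68, adjusted p = 0.0263, and adjusted p = 0.329 with an estimated correlation). Without E16 forelimb digit 2 middle the calls ended for Lum (adjusted p = 0.0515), Wnt9a (0.0819), Col11a1 (0.0506), Comp (0.116) and Kit, the melanocyte gene called (0.131), and all but Lum lost theirs in 6 to 12 of the 20 single omissions. Over all genes edgeR called 562, 275 higher and 287 lower in the middle phalanx, of which 95 and 118 differed at least 2-fold. Within a stage the counts were 90 genes at E16 and 38 at E17. With the forelimb libraries only it was 147 genes and with the hindlimb libraries only 310, and DESeq2 called 826 over all libraries. Single omissions gave 283 (without E16 forelimb digit 2 middle) to 655 genes (without E16 forelimb digit 1 proximal), and 7 of the 20 moved the count over 1.5-fold.

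The distal phalanx of digit 2 was then set against the middle one. The distal phalanx had more of the hard keratins and of several digit tip regulators. Krt35 stood at 467 ± 53.8 CPM in the distal and 5.35 ± 1.15 CPM in the middle phalanx (n = 4 each, log2 fold change 6.42 ± 0.45, adjusted p = 3.02e-08). Sp7 stood at 49.6 ± 20 against 2.84 ± 0.654 CPM (4.06 ± 0.29, adjusted p = 4.29e-08) and Msx1 at 430 ± 172 against 74.8 ± 30.7 CPM (2.54 ± 0.15, adjusted p = 4.44e-09). Gdf5 stood at 10.4 ± 1.88 against 70.4 ± 41.2 CPM (-2.55 ± 0.33, adjusted p = 1.33e-05), and all 4 genes differed in the same direction in 4 of 4 pairs.

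In the nail and hard keratin list 15 of 16 rose and 1 fell, alike adjusted over the list alone (median 5.48, the same with 2 members at 0 placed at their bounds, adjusted p = 5.09e-11, and adjusted p = 0.0414 with an estimated correlation). Krt81 and Krt83 had no counts in the middle phalanx and were at least 13200-fold and 9030-fold higher in the distal phalanx. These folds are of means, and Krt81 was not at 20 CPM or more in every digit 2 distal library. In the hypertrophic cartilage list 7 of 12 rose, against 7 up and 1 down adjusted over the list alone (median 1.4, adjusted p = 0.00102, and adjusted p = 0.0414 with an estimated correlation). Alpl was at 3.22 ± 0.26. The call of Ihh ended without E16 forelimb digit 2 distal (adjusted p = 0.0693), and in 11 of the 20 single omissions. In the osteoblast and bone matrix list 7 of 13 rose and 5 fell, alike adjusted over the list alone (median 0.36), and the list was not past the test (adjusted p = 0.309). Its share of counts was lower in distal phalanges, 0.78% ± 0.151 against 1.48% ± 0.304 in middle ones at E16 and 0.702% ± 0.124 against 1.3% ± 0.247 at E17 (n = 2 each). In the BMP response list 8 of 11 rose and 1 fell, or 9 and 1 adjusted over the list alone (median 0.79, adjusted p = 0.000295, and adjusted p = 0.094 with an estimated correlation). Bambi was at 2.59 ± 0.14 and Grem1, a secreted BMP antagonist, at -6.42 ± 0.73. In the distal digit tip patterning list 10 of 19 rose and 5 fell, or 11 and 6 adjusted over the list alone (median 0.43, adjusted p = 0.00987, and adjusted p = 0.261 with an estimated correlation). Dlx5 was at 2.14 ± 0.13. Erythroid genes rose in 10 of 10 members, 10 adjusted over the list alone (median 1.16, adjusted p = 2.75e-05, and adjusted p = 0.335 with an estimated correlation).

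In the epidermis list 6 of 16 rose and 1 fell, alike adjusted over the list alone (median 0.3, adjusted p = 0.0189, and adjusted p = 0.665 with an estimated correlation). Trp63, the regulator of epidermal stem cells, rose by 0.59 ± 0.09. In the skeletal muscle list 3 of 16 rose, 8 adjusted over the list alone (median 1.48, adjusted p = 0.00578, and adjusted p = 0.651 with an estimated correlation). Ckm rose by 1.6 ± 0.44. The calls of Tnnt3 and Mylpf, the other members called, ended without E16 forelimb digit 2 distal (adjusted p = 0.0628 and 0.0818), and in 5 and 12 of the 20 single omissions. The muscle share was 0.00966% ± 0.000382 in the distal and 0.0039% ± 7.07e-06 in the middle phalanx at E16, and 0.0306% ± 0.00219 and 0.0112% ± 0.00319 at E17 (n = 2 each).

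All 12 endothelium members were lower in the distal phalanx, 12 adjusted over the list alone (median -0.8, adjusted p = 2.82e-09, and adjusted p = 0.0414 with an estimated correlation). Kdr, a VEGF receptor, was at -1.05 ± 0.08. In the tendon and ligament list 8 of 11 fell, 8 adjusted over the list alone (median -1.19, adjusted p = 2.75e-05, and adjusted p = 0.023 with an estimated correlation). Chodl fell by 4.43 ± 0.45. The call of Scx ended without E16 forelimb digit 2 distal (adjusted p = 0.0647), among 3 such libraries. In the macrophage list 10 of 12 fell, 10 adjusted over the list alone (median -0.83, adjusted p = 8.09e-05, and adjusted p = 0.261 with an estimated correlation). Lyz2 fell by 1.31 ± 0.17. In the joint and articular list 8 of 17 fell and 2 rose, or 10 and 2 adjusted over the list alone (median -0.65, adjusted p = 0.00987, and adjusted p = 0.291 with an estimated correlation). Osr1 fell by 2.67 ± 0.31. In the cartilage matrix list 8 of 18 fell and 1 rose, alike adjusted over the list alone (median -0.66, adjusted p = 0.041, and adjusted p = 0.636 with an estimated correlation). Sox6 was at -0.93 ± 0.13. In the cell cycle list 6 of 20 fell, 6 adjusted over the list alone (median -0.16, adjusted p = 0.0112, and adjusted p = 0.634 with an estimated correlation). Mcm6 fell by 0.26 ± 0.06. The count over all genes was 4920 in edgeR, 2424 higher and 2496 lower in the distal phalanx, of which 634 and 858 differed at least 2-fold. Within a stage it was 2499 genes at E16 and 2526 at E17. With the forelimb libraries only it was 3147 and with the hindlimb libraries only 3408.

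The 2 digits were compared first at their distal phalanges. The genes Hoxd10, Hoxd11 and Hoxd12 and 3 hard keratins were lower in digit 1. Hoxd11 stood at 2.56 ± 0.887 CPM in digit 1 and 22.8 ± 7.34 CPM in digit 2 (n = 4 each, log2 fold change -3.13 ± 0.3, adjusted p = 5.26e-05). Hoxd10 stood at 1.57 ± 0.214 against 10.7 ± 5.53 CPM (-2.68 ± 0.27, adjusted p = 7.73e-05) and Hoxd12 at 3.74 ± 2.35 against 27.5 ± 3.3 CPM (-2.96 ± 0.37, adjusted p = 0.00114). Krt86, a hard keratin, stood at 0.401 ± 0.644 against 47.2 ± 66.1 CPM (-6.27 ± 1.03, adjusted p = 0.00621), and all 4 were lower in 4 of 4 pairs.

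In the list of HoxD and HoxA 5-prime genes these 3 HoxD genes fell, against 3 down and 2 up adjusted over the list alone. The list was not past the test (median 0.01, mean -0.61, adjusted p = 0.155). Hoxd13 stood at 100 ± 54 against 109 ± 42.5 CPM (-0.14 ± 0.21, adjusted p = 0.923), with the sign reversed in the hindlimb alone (0.47, adjusted p = 0.187). In the nail and hard keratin list 3 of 16 fell and 1 rose, against 12 down and 1 up adjusted over the list alone (median -1.92, adjusted p = 1e-12, and adjusted p = 0.0517 with an estimated correlation). Krt34 was at -2.77 ± 0.4. The call of Krt33b ended without E16 forelimb digit 1 distal (adjusted p = 0.122), E17 forelimb digit 1 distal (0.0809) or E17 forelimb digit 2 distal (0.0566). The share of counts in this list was 0.361% ± 0.041 in digit 1 and 0.577% ± 0.0453 in digit 2 at E16, and 0.662% ± 0.0742 and 0.889% ± 0.0445 at E17 (n = 2 each). In the osteoblast and bone matrix list 2 of 13 fell, 6 adjusted over the list alone (median -0.19, adjusted p = 0.000627, and adjusted p = 0.0442 with an estimated correlation). These were Ifitm5 and Omd, at -1.9 ± 0.39 and -1.04 ± 0.23, and both calls ended without E16 forelimb digit 1 distal (adjusted p = 0.103 and 0.112), among other libraries.

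In the distal digit tip patterning list 1 of 19 fell, against 6 down and 2 up adjusted over the list alone (median -0.15, adjusted p = 0.00491, and adjusted p = 0.291 with an estimated correlation). It was Bambi at -0.68 ± 0.13, whose call ended without E16 forelimb digit 1 distal (adjusted p = 0.0649), among other libraries. In the joint and articular list 1 of 17 rose, 1 adjusted over the list alone (median 0.17, adjusted p = 0.0488, and adjusted p = 0.433 with an estimated correlation). It was Barx1, whose call ended without E16 forelimb digit 1 distal (adjusted p = 0.07), E16 forelimb digit 2 distal (0.0616) or E17 forelimb digit 1 distal (0.0514). Among the highest fold changes Cntfr, a receptor subunit for a neurotrophic factor, stood at 8.03 ± 5.89 against 1.27 ± 0.726 CPM (2.47 ± 0.37, adjusted p = 0.0032), and Tub, Dio3 and Pcdh10 were at 1.81 ± 0.24, 1.66 ± 0.23 and 1.63 ± 0.21. In all, edgeR called 222 genes, 102 higher and 120 lower in digit 1, of which 35 and 63 differed at least 2-fold. Within a stage the counts were 56 genes at E16 and 0 at E17, where 1126 genes had an unadjusted p under 0.05 in edgeR and no other tool was run. The count was 50 and 88 without E16 forelimb digit 1 distal and digit 2 distal, and 67 and 147 without those of E17. It was 300 without E16 forelimb digit 1 proximal, and 391 without the 2 forelimb digit 1 proximal libraries, a choice made after seeing the data. With the forelimb libraries only it was 239 genes and with the hindlimb libraries only 13, and DESeq2 called 476 over all libraries.

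**Figure D3:**
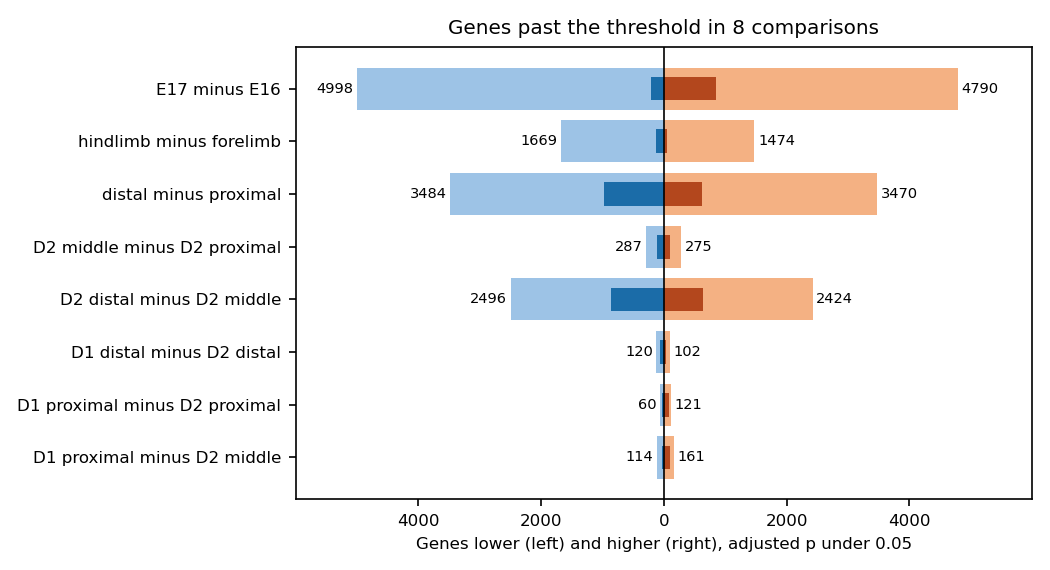
Genes past an adjusted p of 0.05 in the 8 comparisons, higher to the right and lower to the left in pale bars with their numbers, and those that differed at least 2-fold in dark bars. Stage gave the most genes and digit 1 proximal against digit 2 proximal the fewest.

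Digit 1 has 2 phalanges, which raises the question which phalanx of digit 2 its proximal one is nearer to, and it was compared with each. Against digit 2 proximal, 3 HoxD genes and a tendon gene were lower and muscle genes were higher. Hoxd12 stood at 3.97 ± 2.42 CPM in digit 1 proximal and 84 ± 22.9 CPM in digit 2 proximal (n = 4 each, log2 fold change -4.48 ± 0.39, adjusted p = 6.25e-06). Hoxd10 stood at 1.53 ± 0.573 against 29 ± 8.8 CPM (-4.17 ± 0.29, adjusted p = 4.7e-07), Hoxd11 at 3 ± 1.32 against 58.3 ± 22.7 CPM (-4.15 ± 0.31, adjusted p = 1.07e-06) and Kera at 65.6 ± 18.3 against 210 ± 49.6 CPM (-1.69 ± 0.19, adjusted p = 0.000255), all lower in 4 of 4 pairs.

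In the list of HoxD and HoxA 5-prime genes 4 of 12 fell, against 6 down and 4 up adjusted over the list alone (median -0.38, adjusted p = 0.000792, and adjusted p = 0.224 with an estimated correlation). Hoxd13 stood at 209 ± 114 against 280 ± 102 CPM (-0.51 ± 0.21, adjusted p = 0.303). In the anterior-posterior digit patterning list 4 of 26 rose and 1 fell, or 7 and 4 adjusted over the list alone (median 0.22, the same with a member at 0 placed at its bound, adjusted p = 0.0475, and adjusted p = 0.341 with an estimated correlation). The homeobox gene Lhx9 was at 1.51 ± 0.18 and Tbx15 at -1.14 ± 0.17. In the tendon and ligament list 4 of 11 fell, 7 adjusted over the list alone (median -0.47, adjusted p = 6.59e-09, and adjusted p = 0.00161 with an estimated correlation). Fmod fell by 0.47 ± 0.07. In the cartilage matrix list 1 of 18 fell, 8 adjusted over the list alone (median -0.56, adjusted p = 6.39e-06, and adjusted p = 0.224 with an estimated correlation). Col11a1 fell by 0.7 ± 0.11. In the osteoblast and bone matrix list 4 of 13 fell, 5 adjusted over the list alone (median -0.3, adjusted p = 0.00623, and adjusted p = 0.111 with an estimated correlation). Col1a2 fell by 0.42 ± 0.06. In the Hedgehog response list 1 of 7 fell, 1 adjusted over the list alone (median -0.39, adjusted p = 0.0108, and adjusted p = 0.217 with an estimated correlation). It was Foxc2, whose call ended without E16 forelimb digit 1 proximal (adjusted p = 0.102), among 5 such libraries. Without E16 forelimb digit 2 proximal the calls ended for Hoxd9 (adjusted p = 0.0676), Zic2 (0.118), Tnmd (0.0676) and Col1a1 (0.0539), and without E17 forelimb digit 2 proximal for Omd (0.0546).

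Lists past the test with no member called over all genes were endothelium (median -0.22, adjusted p = 5.31e-06, and adjusted p = 0.111 with an estimated correlation), erythroid (0.65, 5 of 10 higher adjusted over the list alone, adjusted p = 2.66e-06, and adjusted p = 0.249 with an estimated correlation) and immediate early and heat shock (-0.13, adjusted p = 0.0148, and adjusted p = 0.341 with an estimated correlation).

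In the skeletal muscle list 15 of 16 rose, 16 adjusted over the list alone (median 3.69, adjusted p = 3.63e-22, and adjusted p = 0.111 with an estimated correlation). Myh8, a developmental myosin, stood at 97.6 ± 140 against 1.56 ± 1.21 CPM (5.46 ± 0.95, adjusted p = 0.0106) and Acta1, skeletal muscle actin, at 162 ± 214 against 9.7 ± 6.07 CPM (3.72 ± 0.63, adjusted p = 0.0101), both higher in 4 of 4 pairs. The muscle share of the forelimb digit 1 proximal libraries was 0.132% at E16 and 0.422% at E17, against 0.00559% and 0.0175% in the hindlimb. Both calls ended without E16 forelimb digit 2 proximal (adjusted p = 0.0581 for Myh8 and 0.0502 for Acta1) or E17 forelimb digit 2 proximal (0.0546 and 0.0504). So did those of Actc1, Myh3, Neb and Ttn without either library (adjusted p = 0.0546 to 0.107). In all, edgeR called 181 genes, 121 higher and 60 lower in digit 1 proximal, of which 84 and 22 differed at least 2-fold. The count was 34 without the 2 forelimb digit 1 proximal libraries, a choice made after seeing the data, and within a stage it was 10 genes at E16 and 11 at E17. With the forelimb libraries only it was 311 genes and with the hindlimb libraries only 39, and DESeq2 called 419 over all libraries. Single omissions gave 36 (without E16 forelimb digit 2 proximal) to 285 genes (without E17 hindlimb digit 1 proximal), and 7 of the 20 moved the count over 1.5-fold.

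Against digit 2 middle the same 3 HoxD genes were lower in digit 1 proximal, muscle genes were higher and nail keratin was lower. Hoxd12 stood at 3.97 ± 2.42 against 55.4 ± 13.7 CPM (n = 4 each, log2 fold change -3.9 ± 0.38, adjusted p = 3.81e-05), Hoxd11 at 3 ± 1.32 against 40.6 ± 18.8 CPM (-3.62 ± 0.31, adjusted p = 7.29e-06) and Hoxd10 at 1.53 ± 0.573 against 15.8 ± 6.27 CPM (-3.28 ± 0.28, adjusted p = 7.29e-06). Krt36 stood at 3.78 ± 3.33 against 39.3 ± 20.1 CPM (-3.66 ± 0.59, adjusted p = 0.00404). Mab21l1, a gene of eye development, stood at 10.1 ± 1.39 against 1.13 ± 0.343 CPM (3.2 ± 0.34, adjusted p = 0.000106), and each of the 5 genes had the same sign in 4 of 4 pairs.

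In the list of HoxD and HoxA 5-prime genes 3 of 12 fell, against 4 down and 1 up adjusted over the list alone (median -0.26, adjusted p = 2.53e-05, and adjusted p = 0.117 with an estimated correlation). Hoxd13 stood at 209 ± 114 against 164 ± 57.8 CPM (0.24 ± 0.21, adjusted p = 0.656), with the sign reversed at E17 alone (-0.05, adjusted p = 0.989). In the distal digit tip patterning list 4 of 19 fell, against 6 down and 2 up adjusted over the list alone (median -0.31, adjusted p = 2.53e-05, and adjusted p = 0.117 with an estimated correlation). Tfap2b fell by 0.76 ± 0.11 and Wnt5a by 0.82 ± 0.14. The call of Sp8 ended without E16 forelimb digit 2 middle (adjusted p = 0.114), among 4 such libraries. In the canonical Wnt response list 2 of 13 fell, against 7 down and 1 up adjusted over the list alone (median -0.44, adjusted p = 0.000115, and adjusted p = 0.117 with an estimated correlation). These were Wif1 and Dkk2, whose calls ended without the same library (adjusted p = 0.054 and 0.186), and in 3 and 8 of the 20 single omissions. In the Hedgehog response list 1 of 7 fell, 1 adjusted over the list alone (median -0.47, adjusted p = 0.0022, and adjusted p = 0.117 with an estimated correlation). Foxc2 fell by 1 ± 0.15. In the epidermis list 2 of 16 fell, 2 adjusted over the list alone (median -0.29, adjusted p = 1.22e-05, and adjusted p = 0.298 with an estimated correlation). These were Epcam and Krt5, whose calls also ended without E16 forelimb digit 2 middle (adjusted p = 0.0989 and 0.171), and in 3 and 14 omissions. In the nail and hard keratin list 1 of 16 fell, 1 adjusted over the list alone (median -0.52, the same with a member at 0 placed at its bound, adjusted p = 0.00396, and adjusted p = 0.323 with an estimated correlation). Krt17 fell by 1.14 ± 0.2. In the osteoblast and bone matrix list 1 of 13 fell, 5 adjusted over the list alone (median -0.24, adjusted p = 0.00396, and adjusted p = 0.117 with an estimated correlation). Omd fell by 1.99 ± 0.28.

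In the HoxC list 1 of 7 fell, 3 adjusted over the list alone (median -0.45, adjusted p = 0.00388, and adjusted p = 0.117 with an estimated correlation). It was Hoxc9, whose call ended without E16 forelimb digit 2 middle (adjusted p = 0.174), and in 8 of the 20 single omissions. In the melanocyte list 1 of 4 rose, 2 adjusted over the list alone (median 0.95, adjusted p = 0.0183, and adjusted p = 0.201 with an estimated correlation). It was Pmel, whose call ended without the same library (adjusted p = 0.173), and in 13 omissions. No member was called in the lists of BMP response (median -0.19, adjusted p = 0.0445, and adjusted p = 0.298 with an estimated correlation), endothelium (-0.17, adjusted p = 0.00211, and adjusted p = 0.201 with an estimated correlation) and erythroid genes (0.44, adjusted p = 0.00282, and adjusted p = 0.438 with an estimated correlation), though all 3 were past the test.

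In the skeletal muscle list 14 of 16 rose, 16 adjusted over the list alone (median 3.08, adjusted p = 5.46e-17, and adjusted p = 0.117 with an estimated correlation). Neb, the thin filament protein nebulin, was at 42.8 ± 50.3 against 0.345 ± 0.148 CPM (6.02 ± 1.13, adjusted p = 0.00989). The muscle share was 0.132% and 0.422% in the forelimb digit 1 proximal libraries, and the call of Neb ended without E16 forelimb digit 2 middle (adjusted p = 0.0584) or E17 forelimb digit 2 middle (adjusted p = 0.0588). The calls of Acta1, Actc1, Myh3, Myh8 and Ttn also ended without either library (adjusted p = 0.067 to 0.114). In all, edgeR called 275 genes, 161 higher and 114 lower, of which 107 and 36 differed at least 2-fold. The count was 50 without the 2 forelimb digit 1 proximal libraries, a choice made after seeing the data, and within a stage it was 11 genes at E16 and 0 at E17, where 1149 genes had an unadjusted p under 0.05 in edgeR and no other tool was run. With the forelimb libraries only the count was 588 genes and with the hindlimb libraries only 36, and DESeq2 called 620 over all libraries. Single omissions gave 90 (without E16 forelimb digit 2 middle) to 456 genes (without E17 hindlimb digit 1 proximal), and 6 of the 20 moved the count over 1.5-fold.

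The distance of the proximal phalanx of digit 1 from each phalanx was measured over all tested genes. Its root mean square difference was 0.591 ± 0.16 log2 CPM from digit 2 middle and 0.565 ± 0.147 from digit 2 proximal (SD, n = 4 stage and limb sets), where middle and proximal lay 0.538 ± 0.0148 apart. The limbs differed in this. In the forelimb it lay 0.738 and 0.721 from digit 2 middle and 0.698 and 0.685 from digit 2 proximal at E16 and E17, farther than these lay from each other (0.556 and 0.544). In the hindlimb it lay 0.448 and 0.458 from middle and 0.417 and 0.459 from proximal, nearer than these lay to each other (0.528 and 0.524). The forelimb libraries are the muscle-rich ones. The difference of the distances was 0.0262 ± 0.0186 (exact sign-flip p = 0.25), above 0, and so nearer digit 2 proximal, in 3 of 4 sets. Without the genes of the muscle list, a choice made after seeing the data, it was 0.0281 (exact sign-flip p = 0.125). On the digit 2 axis its position was 0.468 ± 0.0636, which the test did not tell apart from the midpoint 0.5 (exact sign-flip p = 0.5). The sets were at 0.454 and 0.404 for E16 forelimb and hindlimb and at 0.459 and 0.556 for E17 forelimb and hindlimb, over 173 to 301 axis genes. The smallest p this design allows is 0.125.

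**Figure D4:**
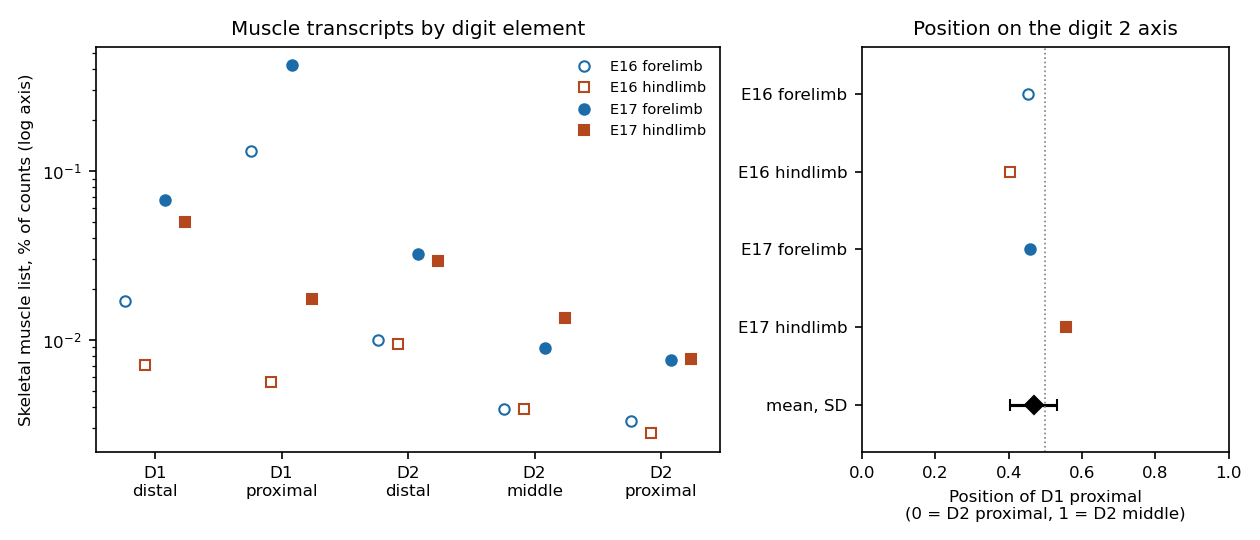
Left, share of counts in the skeletal muscle list per library on a log axis, with colour and shape for the limb and filled points for E17. Right, position of digit 1 proximal between digit 2 proximal (0) and digit 2 middle (1) in the 4 stage and limb sets, with the mean ± SD, and the values lie between 0.404 and 0.556.

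The interaction fits asked whether these differences themselves changed between stages or limbs. For stage by position the 5 genes with the smallest adjusted p were Ebf3 (log2 difference 1.78 ± 0.21), Ebf2 (2.42 ± 0.32), Osr1 (1.21 ± 0.16), Lce1a1 (-9.15 ± 1.14) and Lce1m (-11.84 ± 1.41), each at adjusted p = 0.00933. Ebf2 and Ebf3, early B-cell factors also made in connective tissue, had a distal deficit that was smaller at E17. The calls of all 5 genes ended without E16 forelimb digit 2 proximal (adjusted p = 0.0514 for Ebf3 and 0.06 for the others), which left 0 genes in edgeR, with 1034 genes at an unadjusted p under 0.05 and no other tool run. In the erythroid list the median log2 difference was 0.88, with no member called over all genes and 9 of 10 higher adjusted over the list alone (adjusted p = 1.03e-12, and adjusted p = 0.239 with an estimated correlation). The erythroid share of distal phalanges was 1.2% ± 0.233 in digit 1 and 1.32% ± 0.00707 in digit 2 at E16, and 3.04% ± 0.516 and 2.61% ± 0.191 at E17 (n = 2 each). Over the other lists past the test the medians were 0.25 for joint and articular, -0.22 for epidermis, 0.49 for nail and hard keratin, -0.15 for cell cycle, 0.47 for macrophage, -0.52 for melanocyte and 0.33 for mitochondrially encoded genes, and none was past it with an estimated correlation (adjusted p = 0.239 to 0.6). In all, edgeR called 33 genes, 12 higher and 21 lower. DESeq2 called 218, and 9 of the 20 single omissions moved the edgeR count over 1.5-fold, with the highest, 68, without E16 hindlimb digit 1 proximal.

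For stage by limb edgeR called 0 genes, with 1814 genes at an unadjusted p under 0.05 and a smallest adjusted p of 0.296, and DESeq2 called 29 of the 5645 genes that its own filter left, against 14872 tested in edgeR. Without E16 forelimb digit 2 middle edgeR called 146. The cartilage matrix list (median -0.38, adjusted p = 0.0123, and adjusted p = 0.968 with an estimated correlation) and the mitochondrially encoded list (median 0.38, adjusted p = 0.0298, and adjusted p = 0.968 with an estimated correlation) were past the test with no member called.

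For limb by digit, the contrast of digit 1 with digit 2 was lower for muscle genes in the hindlimb than in the forelimb. Myh8 differed by -3.18 ± 0.23 (adjusted p = 1.54e-05), Myh3 by -3.9 ± 0.34 (adjusted p = 9.16e-05), Actc1 by -2.5 ± 0.25 (adjusted p = 0.000313) and Atp2a1, the calcium pump of fast muscle, by -3.2 ± 0.35 (adjusted p = 0.000744). Socs2, an inhibitor of cytokine signals, differed by -1.17 ± 0.13 (adjusted p = 0.000744). In the skeletal muscle list 11 of 16 were lower, 15 adjusted over the list alone (median -2.14, adjusted p = 5.27e-36, and adjusted p = 0.00949 with an estimated correlation). Muscle transcripts took 0.132% and 0.422% of the counts of the forelimb digit 1 proximal libraries at E16 and E17, against 0.00559% and 0.0175% in the hindlimb. In the list of HoxD and HoxA 5-prime genes 1 of 12 was higher, 3 adjusted over the list alone (median 0.44, adjusted p = 8.19e-08, and adjusted p = 0.00667 with an estimated correlation). The nail and hard keratin list was also past the test with no member called (median 1.05, adjusted p = 2.17e-05, and adjusted p = 0.232 with an estimated correlation). Medians of the other lists past the test were -0.25 for cartilage matrix, 0.12 for canonical Wnt response, 0.17 for cell cycle and -0.45 for macrophage, with adjusted p = 0.105 to 0.735 with an estimated correlation. In all, edgeR called 58 genes, 13 higher and 45 lower. DESeq2 called 196. The edgeR count was 98 without E16 forelimb digit 1 proximal, 34 and 33 without E16 hindlimb digit 1 proximal and digit 2 proximal, and 29, 34 and 33 without E17 forelimb digit 1 distal, digit 2 distal and digit 2 proximal. It was 29 and 35 without E17 hindlimb digit 1 proximal and digit 2 proximal.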

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

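The tests of single-exon genes, of AY036118, of swapped libraries, of Krtap proportions and of free reads were chosen after their results were seen, and the margin of 1 SE for AY036118 was added after its value was seen.

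Muscle transcripts were high in the forelimb digit 1 proximal libraries, with Actc1 at 284.4 CPM at E16 and 888.5 CPM at E17 against 11.05 and 36.02 CPM in the hindlimb, and Acta1 at 125.2 and 473.7 CPM against 10.41 and 37.83 CPM. A swap with a digit 2 library was argued against, since Hoxd10, Hoxd11 and Hoxd12 lay below the lowest digit 2 library of the stage in the digit 1 proximal libraries, with 0 exceptions in 4. The 16 muscle genes moved together over the 20 libraries (median pairwise r 0.933, lowest 0.551), and none of them is in another list. Muscle tissue included at dissection is a candidate explanation, and so is a muscle or tendon insertion proper to the forelimb thumb, which was not tested. With 1 library per stage and limb these 2 cannot be separated.

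Krt84 was higher in digit 2 middle than in digit 2 proximal in each of the 4 stage and limb sets, by at least 1580-fold in E16 forelimb, where the proximal library had 0 counts (floor of 3 counts in that library), and by 120-fold, 51.4-fold and 5.21-fold in E16 hindlimb, E17 forelimb and E17 hindlimb. The lowest fold of 5.21 argues against free reads spread evenly between the libraries of a run. Carry-over of distal tissue could not be told apart from expression in the middle phalanx itself, because the other distal genes met neither bound: 37.5% (6 of 16) stood within 3-fold of the 0.821% of the distal level that Krt84 had there, and 18.8% (3 of 16) stood below 0.1 of it. Krtap genes together stood at 22.1% of the counts that carry-over in distal proportions would give (325 of 1470), and at 11.6% to 46% in the 4 sets. By means over the 4 sets, Krtap3-3 stood at 0.416% of its distal level. Krtap3-1, Krtap7-1 and Krtap8-1 stood at 0.0617%, 0.0414% and 0%, over 10-fold below Krt84 and against distal proportions by these means. The share of Krt84 itself differed between sets, from 0.286% in E17 hindlimb to 1.69% in E16 hindlimb, and single genes were not compared within sets. Krt35 and Krt36 stood near Krt84, at 1.15% and 0.989%, and the sums were not below 10% in all 4 sets, which left that explanation open too. Carry-over of nail tissue and an early nail program in the middle phalanx both may explain the keratins.

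Between the stages, 389 single-exon genes had a median log2 fold change of -0.13, outside the central 99% of abundance-matched lists of multi-exon genes (-0.03 to 0.122), which is consistent with annotation or counting that differed between the E16 and E17 tables. AY036118 and LOC118568312 at E17 together reached 2.00 ± 0.266 (SE) times the level of Gm26917 at E16. Alone they stood at 1660 ± 610 and 1750 ± 652 CPM at E17, each near the 1710 ± 357 CPM of Gm26917 at E16 (without TMM scaling, n = 10). The fold change of AY036118 may therefore be a difference of names between the tables. Without coordinates, 1 locus under different names and a true change cannot be told apart. Gm26917 drew attention as a gene of the E16 table only, with 1263491 counts, and LOC118568312 as a gene of the E17 table only, with 1485682. Names found in 1 table only held 0.57% of the counts at E16 and 0.85% at E17. Without single-exon genes the stage count was 9532 against 9788, and no biological explanation was tested.

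The stage by position interaction drew attention because the difference between distal and proximal phalanges itself differed between stages, in 33 genes. Among them were Ebf3 (1.78), Ebf2 (2.42), Osr1 (1.21), Lce1a1 (-9.15) and Lce1m (-11.84), and the erythroid list had a median of 0.88. Chance could not be excluded, since 4 of 34 splits of the libraries gave as many genes, with 256 as the highest other count, and 1 further split could not be estimated. The split with 256 genes parted the libraries exactly by limb, which points to a structure of the samples by limb. The others, with 158 and 66 genes, set 7 hindlimb and 3 forelimb libraries against the reverse, and 8 libraries of a stage and 2 of the other against the reverse. All 3 were unbalanced by limb, so these splits do not measure chance alone. Without E16 forelimb digit 2 proximal edgeR called 0 genes (1034 at an unadjusted p under 0.05), and the highest count was 68, without E16 hindlimb digit 1 proximal.

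The limb by digit interaction drew attention because the difference between the digits differed between limbs, in 58 genes. They included Myh8 (-3.18), Myh3 (-3.9), Actc1 (-2.5), Atp2a1 (-3.2) and Socs2 (-1.17), and the medians were -2.14 for the skeletal muscle list and 0.44 for HoxD and HoxA 5-prime genes. In 1 of 34 splits, the real one, as many genes were called, and 1 further split could not be estimated. The margin was narrow, with 54 genes in the highest other split. The other splits were fitted with a further term for limb, so the counts are not strictly alike. Chance was therefore not excluded. The count itself ranged from 29 to 98 when single libraries were left out, below 54 in 17 of the 20 omissions (for which no splits were run), the lowest without E17 forelimb digit 1 distal or E17 hindlimb digit 1 proximal and the highest without E16 forelimb digit 1 proximal. DESeq2 called 196.

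For the other counts 1 split was as large, the real one, in each case. The splits broke the matching of libraries, and the real effects entered the spread within the other splits. They therefore do not exclude chance, and they do not cover differences between pools. Over 100 splits the real count and the highest other were 9788 against 4928 for stage, 3143 against 66 for limb and 6954 against 2963 for position. Over 35 splits they were 562 against 0 for digit 2 middle and proximal, 4920 against 1 for digit 2 distal and middle and 222 against 21 for the 2 distal phalanges. They were 181 against 15 for digit 1 proximal and digit 2 proximal, and 275 against 81 for digit 1 proximal and digit 2 middle. The counts of 0 are from edgeR. For stage by limb, where edgeR called 0 genes (1814 at an unadjusted p under 0.05, and 29 in DESeq2 over the 5645 genes that its own filter left), all 100 splits reached the real count by its size alone (highest 20), so they decide nothing about chance. Without E16 forelimb digit 2 middle edgeR called 146.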

How the results depend on the processing

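Leaving out the 2 muscle-rich libraries, the single-exon genes or the muscle list was chosen after seeing the data. Over the settings of 527 pairs of a named gene and a comparison 13271 results kept direction and side of the threshold, 1059 were weaker, 56 stronger and 7 reversed.

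Counts that moved over 1.5-fold were, with E16 libraries only, limb 1560, position 4287, digit 2 middle against proximal 90, digit 2 distal against middle 2499, digit 1 distal against digit 2 distal 56, digit 1 proximal against digit 2 proximal 10 and against digit 2 middle 11. With E17 only they were 188 for limb, 38, 2526, 0 (1126 at an unadjusted p under 0.05 in edgeR), 11 and 0 (1149) in the same order without position. With the forelimb only they were 147, 3147, 311 and 588 for digit 2 middle against proximal, distal against middle, and digit 1 proximal against digit 2 proximal and middle. With the hindlimb only they were 310, 13, 39 and 36 for digit 2 middle against proximal, digit 1 distal against digit 2 distal, and digit 1 proximal against both. These settings hold fewer libraries.

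DESeq2 called 476, 419 and 620 genes for the 3 comparisons between digits, 218 for stage by position, 29 for stage by limb (of 5645 genes left by its own filter) and 196 for limb by digit. The cause was not tested. Without the 2 muscle-rich libraries the 3 comparisons between digits gave 391, 34 and 50. With an estimated correlation 8 list tests passed against 81 with the preset one.

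Signs reversed for Tbx5 in digit 2 middle against proximal in the forelimb (-0.12), for Gli1 (0.07, hindlimb), Cdh5 (0.01, E16) and Hoxd13 (-0.05 at E17, -0.06 in the forelimb) in digit 1 proximal against digit 2 middle, and for Hoxd13 in digit 1 distal against digit 2 distal (0.47 in the hindlimb, and -0.35 to 0.05 over single omissions, the highest without E16 forelimb digit 1 distal). None of these passed the test, and the cause was not tested.

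Leaving out each library in turn gave 9414 to 9700 genes for stage, 2293 to 3196 for limb, 6494 to 6916 for position, 283 to 655 for digit 2 middle against proximal, 3927 to 5310 for distal against middle, 50 to 300 for digit 1 distal against digit 2 distal, 36 to 285 and 90 to 456 for digit 1 proximal against digit 2 proximal and middle, 0 to 68 for stage by position, 0 to 146 for stage by limb and 29 to 98 for limb by digit. The distance difference ranged from 0.0218 to 0.0353 and the axis position from 0.439 to 0.49.

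Abbreviated, F is forelimb, H hindlimb, and 1d, 1p, 2d, 2m, 2p the phalanges. Omissions that moved a count over 1.5-fold were, for digit 2 middle against proximal, E16 F2m 283, F2p 314, H2m 347, H2p 340 and E17 F2m 351, H2m 357, H2p 327. For digit 1 distal they were E16 F1d 50, F2d 88 and E17 F1d 67, F2d 147. For digit 1 proximal against digit 2 proximal they were E16 F1p 83, F2p 36, H2p 108 and E17 F1p 111, F2p 47, H1p 285, H2p 67, and against middle E16 F1p 142, F2m 90 and E17 F1p 133, F2m 100, H1p 456, H2m 175. For stage by position they were E16 F2p 0 (1034 at an unadjusted p under 0.05 in edgeR), H1p 68 and E17 F2d 18, F2m 18, H1d 17, H1p 21, H2d 18, H2m 18, H2p 15, for stage by limb E16 F2m 146, and for limb by digit E16 F1p 98, H1p 34, H2p 33 and E17 F1d 29, F2d 34, F2p 33, H1p 29, H2p 35.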
